A study of Mus musculus with 8 samples.

How the data were processed

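The study measured ribosome-protected fragments in mouse brain at postnatal day 5, with 3 SMN immunoprecipitates, 1 IgG immunoprecipitate, 2 RiboLace libraries and 2 polysome libraries. The deposited table holds raw read counts per Ensembl transcript for the 8 libraries, together with transcript, UTR and coding lengths, per the file headers. Per the submitters' processing notes, Trimmomatic 0.36, Bowtie2 2.2.6 and SAMtools were used with the GRCm38.p4 build. How reads matching several transcripts were counted is not given in the sources used here. The table lists 109463 transcripts of 45578 genes, of which 21874 have a protein-coding transcript and 25514 transcripts have no read in any library. Library totals over all transcripts were 403554, 304615 and 703704 for the SMN replicates, 632823 for IgG, 122993 and 105720 for RiboLace and 3546905 and 4936856 for polysomes. Totals over 1 transcript per gene, noncoding genes included, were 198507, 188891, 348656, 320993, 69102, 58382, 1851269 and 2549857 in the same order. The counts of isoforms, and of near-identical genes such as the alpha-tubulins, therefore appear to hold the same reads more than once, and summed totals exceed the number of reads. No column of another series was used.

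Each gene was represented by its protein-coding transcript with the highest library-scaled total over the 8 libraries, a choice made after the table was seen to list transcripts. Symbols were taken from the transcript names in the table. Counts per gene were analysed with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust fitting, two-sided, TMM scaling, filterByExpr with a minimum count of 10) on the groups compared and no others. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error is the size of the log2 fold change divided by the square root of F. CPM in the gene comparisons are TMM-scaled, and the CPM of Smn1 per library are relative to the total over coding genes. With 1 IgG library, its spread was assumed to equal that of the SMN libraries. Where a group had no read, the fold was bounded with a floor of 3 counts over the libraries of the group together, set against the pooled reads of the other group, which can differ slightly from the mean CPM printed. Gene lists, 27 in number, were tested with camera from edgeR and limma 3.58.1 at a preset correlation of 0.01, where at least 5 members had been tested, with a Benjamini-Hochberg adjustment over lists. Median log2 ratios per library used a prior count of 2.

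The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule named Smn1, the 10 genes with the largest fold change in each direction among called genes with a mean log2 CPM of 5 or more and no overlap between groups, and up to 4 members of each list described (3 were used), passing over predicted genes. Where no gene qualified, the 3 with the smallest p were named as not past the test. The alternatives were DESeq2 1.42.0, library totals, no filter or a minimum count of 50, all 8 libraries in 1 fit, limma-voom, the replicate number as a block, each library left out in turn, transcripts as deposited, counts summed per gene and, added after seeing the data, all genes with noncoding ones included and the SMN-enriched set without histone genes. The labels give the same replicate numbers to different groups without stating that they share an animal or day.

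The scripts were tested on simulated counts with the real means, library sizes and spreads, in which 200 genes per comparison were changed. For the SMN immunoprecipitate against IgG (5517 genes), 0 of 100 genes changed 2-fold and 28 of 100 changed 4-fold were recovered, with 1 false call. For RiboLace against polysomes (10807 genes), the numbers were 7 and 31 of 100, with 2 false calls. For the SMN immunoprecipitate against polysomes (6484 genes), they were 58 and 91 of 100, with 6 false calls. Control-genotype RiboLace and polysome libraries of other series were not used here. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 served for reading the table and drawing.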

Results

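Ribosome-protected fragments were sequenced from brains of mice at postnatal day 5 in 8 libraries. The mice belonged to the Taiwanese model of spinal muscular atrophy (SMA), a motor neuron disease caused by low levels of the survival motor neuron protein SMN. In this model the mouse Smn gene is disrupted and the human SMN2 transgene supplies a low amount of SMN. The 3 SMN immunoprecipitates and the 1 IgG immunoprecipitate came from healthy Smn+/-; SMN2tg/0 brains, in which ribosomes were digested with RNase I, pelleted and pulled down with an anti-SMN antibody or with IgG. The 2 RiboLace libraries, from a capture of actively translating ribosomes, and the 2 polysome libraries, from ribosomes of sucrose gradients, came from Smn-/-; SMN2tg/0 brains. The labels call the libraries of a group biological replicates.

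Depth differed between the groups. Counted on 1 transcript per protein-coding gene, SMN replicates 1 to 3 held 138239, 133295 and 237760 reads and the IgG library held 206690. RiboLace replicates 1 and 2 held 47846 and 39375 reads, and polysome replicates 1 and 2 held 1661834 and 2295393. A floor of 3 counts for a gene without a read equals 76.2 counts per 1e+06 reads (CPM) in RiboLace replicate 2, against 1.31 CPM in polysome replicate 2. Coding genes took 69.5% ± 1.20 (SD, n = 3) of the reads in the SMN libraries, 64.4% in IgG, 68.3% ± 1.27 (SD, n = 2) in RiboLace and 89.9% ± 0.177 (SD, n = 2) in polysomes. Among the immunoprecipitates, SMN replicate 2 stood apart. Its counts differed from those of SMN replicate 3 with a chi-square of 3.65 per gene, whereas IgG and SMN replicate 3 differed with 1.27 per gene and SMN replicates 1 and 3 with 1.42. The RiboLace pair differed with 1.10 per gene, slightly above sampling noise (chi-square test, p = 0.00233), and the pair was kept as 2 replicates.

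Smn1 (ENSMUSG00000021645), the gene disrupted in the SMA mice, was read in each group. It had 159, 97.53 and 143 CPM in SMN replicates 1 to 3, from 22, 13 and 34 reads, and 29.0 CPM in IgG, from 6 reads with an exact 95% Poisson interval of 10.7 to 63.2 CPM. The polysome libraries of SMA brains held 30.7 and 33.5 CPM of Smn1. The RiboLace libraries held 2 reads and 0 reads, which allows up to 93.7 CPM in the second library by the same exact interval. Such intervals and limits cover counting error only. Reads on Smn1 can come from parts of the gene outside the disrupted region or from the SMN2 transgene, so these levels do not check the genotype labels.

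**Figure D1:**
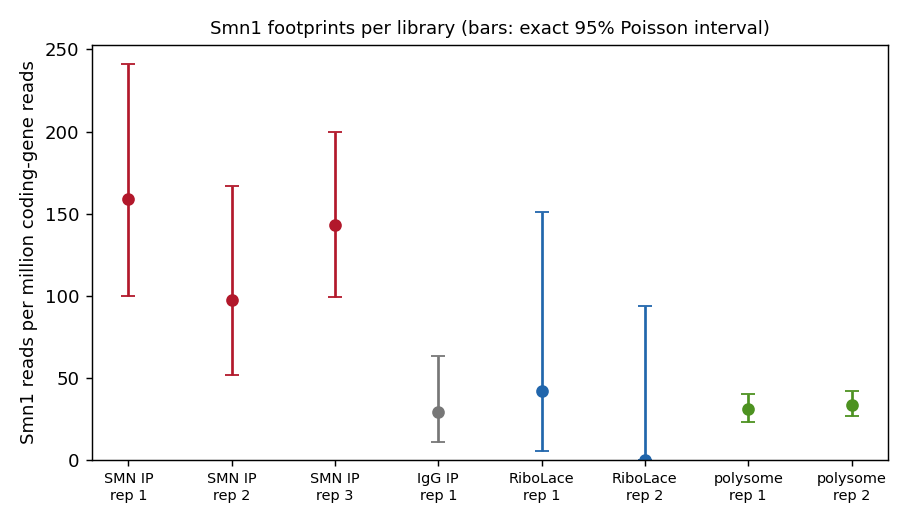
Smn1 CPM over coding-gene reads in each of the 8 libraries, grouped by protocol, with bars for the exact 95% Poisson interval. The SMN libraries sit between 97.53 and 159, above the IgG library at 29.0 and the polysome libraries at 30.7 and 33.5.

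The first comparison set the SMN immunoprecipitate against IgG, the control for unspecific pull-down, and asks which messages sit on ribosomes bound by SMN. No coding gene was called higher in the SMN immunoprecipitate, and 1 of 5517 genes was called lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). That gene was the predicted gene Gm21887, at 93.6 ± 17.6 CPM (SD, n = 3) against 523 CPM in IgG (log2 fold change -2.45, SE 0.48, adjusted p = 0.00221). It was named after its value was seen. Erdr1 had a log2 fold change of -1.61 (SE 0.44, adjusted p = 0.501). Whether reads on Gm21887 and Erdr1 are shared, or come from repeated sequence, was not tested here. At an unadjusted p under 0.05, 99 genes were higher and 49 lower, where 276 would arise by chance, so the test was cautious here. In simulated counts it recovered 0 of 100 genes changed 2-fold and 28 of 100 changed 4-fold. The lack of calls therefore does not show that the SMN and IgG libraries held the same messages. DESeq2 and limma-voom called 0 genes higher as well, and the call of Gm21887 was lost with DESeq2. Smn1 had 153 ± 36.9 CPM (SD, n = 3) against 33.0 CPM in IgG (log2 fold change 2.197, SE 0.72), higher in each of the 3 SMN libraries, with adjusted p = 0.921 by edgeR over all genes. It was the 1 gene past the threshold when adjusted over the list alone among 15 tested members of the SMN complex and Sm ribonucleoprotein list (adjusted p = 0.0351). Without SMN replicate 2, 2 genes were called higher and 3 lower. These were Smn1 (log2 fold change 2.34, adjusted p = 0.0224) and Hap1 (1.64), and Gm21887 (-2.44), Erdr1 (-1.92) and mt-Nd5 (-1.50).

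None of the genes with the smallest unadjusted p among those higher passed the test. Hap1, which encodes a huntingtin-associated trafficking protein, had 636 ± 227 CPM (SD, n = 3) against 160 CPM in IgG. Nap1l5 had 343 ± 250 CPM against 77.0 CPM, and Calb2, the calcium-binding protein calretinin, had 190 ± 109 CPM against 33.0 CPM. The adjusted p of each was 0.501. Among those lower, Dgkz, a diacylglycerol kinase, had a log2 fold change of -1.68 (adjusted p = 0.921) and Utp20, a ribosome biogenesis factor, of -1.83 (adjusted p = 0.9995).

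Of 25 gene lists tested, 6 passed camera with its preset correlation in this comparison, and 0 with an estimated correlation. With an estimated correlation camera takes its degrees of freedom from the few libraries of the fit, not from the number of genes. The mitochondrially encoded list went from camera p = 1.74e-09 to p = 0.0241, though its estimated correlation of -0.046 lay below the preset 0.01. That of histones, at 0.59, lay above it. Loss of calls with an estimated correlation, here and below, thus does not show correlation between genes as its cause. The histone list lay higher in the SMN immunoprecipitate, with 68 of 73 members at a positive log2 fold change and a median of 0.52 (adjusted p = 3.57e-12, and adjusted p = 0.845 with an estimated correlation). Its members with the smallest p encode linker histones: Hist1h1b had a log2 fold change of 2.06, Hist1h1e of 1.71 and Hist1h1a of 2.32, and 1.14, 1.11 and 1.31 without SMN replicate 2. 0 histone genes passed, also when adjusted over the list alone. By library, the histone median was 0.84, 0.66 and 0.046 in SMN replicates 1 to 3, and it was 0.82 without replicate 3. Mitochondrially encoded proteins lay lower, with a median of -1.13 and 1 of 11 members positive (adjusted p = 2.18e-08, and adjusted p = 0.603 with an estimated correlation), and 1 member passed as lower when adjusted over the list alone. Short of the test over all genes, mt-Co2 had 113 ± 50.2 CPM (SD, n = 3) against 303 CPM in IgG, and mt-Nd1 had 110 ± 20.3 CPM against 275 CPM. Markers of other cell types lay higher together with these lists. The medians were 0.94 for oligodendrocyte lineage markers (7 of 8 positive, adjusted p = 0.00228), 0.64 for neural progenitor and cell cycle genes (15 of 17 positive, adjusted p = 4.92e-04) and 0.48 for astrocyte markers (12 of 16 positive, adjusted p = 0.00809). With an estimated correlation each of these had an adjusted p = 0.845. Without SMN replicate 2 the oligodendrocyte and astrocyte medians were 0.57 and 0.23, and without replicate 3 the progenitor median was 1.05. In the oligodendrocyte list, Olig1, a lineage transcription factor, had 232 ± 124 CPM (SD, n = 3) against 99.0 CPM in IgG, and 1 of the 8 members passed when adjusted over the list alone. The list of genes with very long coding regions lay lower with a median of -0.25 (adjusted p = 0.0147, and adjusted p = 0.845 with an estimated correlation). Its members Macf1 and Dst, which encode cytoskeletal linkers, had log2 fold changes of -0.70 and -0.60, and Syne1, a nuclear envelope protein, of 0.76. Without SMN replicate 2 this list did not pass, with a median of -0.12 (camera, adjusted p = 0.0826), and Macf1, Dst and Syne1 had log2 fold changes of -0.36, -0.35 and 0.35. The IgG side of this comparison rests on 1 library, which was assumed to vary like the SMN libraries.

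The second comparison set RiboLace against polysome footprints within SMA brains and asks which messages are over- or under-represented on actively translating ribosomes. RiboLace is a capture and polysomes come from gradients, without a background control here, so the protocol cannot be told apart from active translation. RiboLace libraries held more footprints of tubulin genes. Tuba1a, an alpha-tubulin of developing neurons, had 9714 ± 645 CPM (SD, n = 2) against 2326 ± 286 CPM (SD, n = 2) in polysomes (log2 fold change 2.06, SE 0.14, adjusted p = 9.05e-48). The fit shared its spread estimates (common dispersion 0.00227) between RiboLace and polysome libraries, so such p values do not measure the spread of RiboLace alone. With limma-voom the adjusted p of Tuba1a was 0.161. Tuba1b and Tuba1c were higher by 1.91 and 2.01 on the log2 scale, but near-identical alpha-tubulin genes share reads in this table and their separate values are uncertain. The beta-tubulin gene Tubb2b had 9528 ± 44.6 CPM against 2858 ± 355 CPM, and Tmsb10, an actin-binding thymosin, 781 ± 94.6 CPM against 224 ± 14.1 CPM. The largest folds belonged to Tmem38b, an intracellular cation channel, with 1248 ± 174 CPM against 37.2 ± 0.028 CPM, and Lars2, the mitochondrial leucyl-tRNA synthetase, with 1612 ± 46.8 CPM against 63.6 ± 6.27 CPM. Whether the reads counted on Tmem38b and Lars2 come from rRNA-like or repeated sequence was not tested here, so these values describe the counts and not translation of the 2 genes. Counts on both were also higher in the SMN immunoprecipitate than in polysomes, by 3.44 and 3.60 on the log2 scale. Tmem245, Cyp4x1 and Mtch2 were higher by 3.01, 1.94 and 1.70 on the log2 scale, and the calls of Cyp4x1 and Mtch2 were lost without either RiboLace library. In all, 142 of 10807 genes were higher and 100 lower (edgeR quasi-likelihood test, adjusted p under 0.05).

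**Figure D2:**
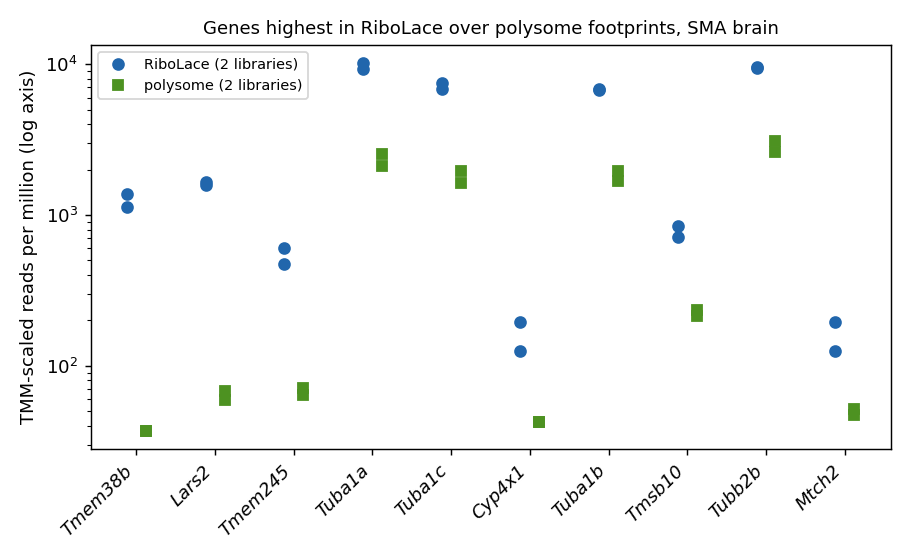
TMM-scaled CPM, on a log axis, of the 10 named genes with the largest fold of RiboLace over polysome footprints in SMA brains, with 1 point per library. Both RiboLace libraries lie above both polysome libraries for each gene, from Tmem38b at 1248 against 37.2 to Mtch2 at 160 against 49.4.

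Of 27 lists tested, 6 passed camera in this comparison, all higher in RiboLace, and 0 with an estimated correlation. In the axon growth and neuronal cytoskeleton list, 19 of 51 members rose and 0 fell, with a median log2 fold change of 0.44 (adjusted p = 1.11e-35, and adjusted p = 0.576 with an estimated correlation). Adjusted over the list alone, 25 rose and 2 fell, and the smallest p belonged to the tubulins. In the histone list, 24 of 76 members rose and 0 fell, with a median of 0.88 (adjusted p = 2.93e-31, and adjusted p = 0.576 with an estimated correlation). Adjusted over the list alone, 40 rose. They included the H4 genes Hist1h4c, at 589 ± 190 CPM (SD, n = 2) against 197 ± 9.93 CPM, and Hist1h4h, at 656 ± 81.7 CPM against 259 ± 15.4 CPM, and histone copies share reads. In the list of blood cell genes, 4 of 8 rose, led by the globin genes Hba-a2 (log2 fold change 1.40), Hbb-bt (1.33) and Hbb-bs (1.30). Globin genes may share reads as well, since Hbb-bt had 58 and Hbb-bs 62 reads in each RiboLace library. The 4 rises may therefore not be separate members of the list. The median of that list was 1.01 and its mean -0.24, which differ in sign (adjusted p = 3.67e-08, and adjusted p = 0.649 with an estimated correlation). With a library left out the median ranged from 0.59 to 1.58. Of 26 other SMA and motor neuron disease genes, 4 rose, among them Stmn2, a microtubule regulator of growing axons (log2 fold change 1.23, adjusted p = 4.67e-11), Gap43, a growth cone protein (0.91), and Hnrnpa2b1, an RNA-binding protein (1.01). Adjusted over the list alone, 4 of the blood cell genes and 5 of the disease genes rose. The disease list had a median of 0.38 (adjusted p = 5.97e-07, and adjusted p = 0.576 with an estimated correlation). Of 84 cytosolic ribosomal protein genes, 0 passed, also when adjusted over the list alone, and their median was 0.19 (adjusted p = 9.82e-05, and adjusted p = 0.652 with an estimated correlation). Rpl38, Rps3a1 and Rpl10 had log2 fold changes of 1.11, 0.90 and 1.05, and over the alternatives these ranged from 0.50 to 1.49, from 0.43 to 1.13 and from -0.56 to 1.64. Of 76 nuclear genes of oxidative phosphorylation, 3 rose, Atp5a1 by 0.84, Atp5b by 0.64 and Cox8a by 0.84 on the log2 scale. The calls of Atp5b and Cox8a were lost without either RiboLace library, with log2 fold changes of 0.36 and 0.44 without replicate 1. Adjusted over the list alone, 4 rose, and the median was 0.12 (adjusted p = 0.00728, and adjusted p = 0.652 with an estimated correlation). The calls of the ribosomal protein and oxidative phosphorylation lists were lost without RiboLace replicate 1 and without either polysome library (camera, adjusted p up to 0.780 and 0.753). Over 6 alternatives their medians ranged from 0.099 to 0.41 and from -0.010 to 0.39. Camera placed both lists higher than the other genes in all 6. A median near 0 is not the level of the other genes, since all genes had a median of -0.29 in the main fit. With a library left out the median of the disease list ranged from 0.17 to 0.61, and that of histones was 0.58 without RiboLace replicate 1. In IgG over the same polysomes, the cytoskeleton list had a median log2 ratio of 0.93, with 44 of 51 members above. A higher median of this list over polysomes was thus not seen in RiboLace alone. IgG came from a Smn+/- brain and the polysomes from Smn-/- brains, so genotype and protocol both differ there. Whether the same change underlies both shifts was not tested. The IgG medians were 0.54 for ribosomal proteins, 0.27 for the disease list, 0.22 for histones, -0.29 for oxidative phosphorylation and -0.38 for blood cell genes.

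Among the lower genes, 17 had no read in either RiboLace library, and those named here were all of this kind. With a floor of 3 counts over both RiboLace libraries set against the pooled polysome reads, Mb21d2 was at least 3.70-fold lower (128 ± 3.60 CPM in polysomes, SD, n = 2, adjusted p = 4.09e-04) and Gab1, an adaptor of receptor tyrosine kinases, at least 2.91-fold lower (99.6 ± 12.6 CPM, adjusted p = 0.00382). Msh6, a mismatch repair protein, was at least 2.66-fold lower, and Cstb, Cdc42ep2, Mfsd2a, Ilvbl, Rer1 and Jag2 between 2.25-fold and 2.52-fold lower by the same bound. Smn1 had a log2 fold change of -0.53 (SE 1.05, adjusted p = 0.882), and a difference was not detectable at this depth. The calls depended on the test: DESeq2 called 192 genes higher and 6 lower, and limma-voom 0 and 0. With the replicate number as a block, 58 were higher and 0 lower, so the lower genes named here lost their calls. Leaving out RiboLace replicate 1 left 31 higher and 2 lower, and leaving out RiboLace replicate 2 left 54 and 1.

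A further test asked whether messages enriched with SMN were placed differently between RiboLace and polysomes of SMA brains. Since 0 genes were called higher than IgG, the set held the 200 genes with the largest SMN over IgG fold change in the upper range of expression, none of them past the test against IgG. Of these 30 were histone genes, which share reads, 7 glial or progenitor markers and 9 subcortical or hindbrain genes. In RiboLace against polysomes 7 of them rose, 6 of which were histones, 11 fell, and their median log2 fold change was -0.25, against -0.29 for the other genes. Camera placed the set lower than the other genes, which differs in sign from the medians, and did not pass (camera p = 0.118, and p = 0.340 with an estimated correlation). Without the histone genes, an alternative chosen after seeing the data, 1 of the other 170 genes rose and 11 fell. Their median was -0.39, and camera placed them lower than the other genes, at -0.29 (camera p = 3.11e-05, and p = 0.0417 with an estimated correlation). With the 500 largest fold changes the median was -0.35, and the set passed camera as lower. Without RiboLace replicate 1 the 200 genes passed as lower too, with a median of -0.43 where the other genes had -0.63. Camera and the medians again differ in sign. These medians compare unlike ranges of expression, since the set was drawn from the upper range and the other genes were not. The median of all genes was -0.29 in the main fit and -0.058 with a minimum count of 50. Without polysome replicate 1 or 2, where 1380 and 1384 genes were tested, the set had medians of -0.076 and -0.011. The other genes then had 0.023 and 0.028.

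The third comparison set the SMN immunoprecipitate against polysome footprints. It is secondary, since genotype and protocol both differ, and the IgG library is given beside it. Several cytoskeletal genes and a collagen gene were among the largest rises in the SMN immunoprecipitate. Dst, a spectraplakin, had 883 ± 323 CPM (SD, n = 3) against 53.5 ± 3.88 CPM (SD, n = 2) in polysomes (log2 fold change 4.06, SE 0.34, adjusted p = 2.00e-06). Macf1 and Plec, of the same protein family, were higher by 3.50 and 4.02 on the log2 scale, Sptbn1, a spectrin, by 3.34, and Dbn1, the actin-binding protein drebrin, by 3.32. Col3a1, a fibrillar collagen, had 1465 ± 107 CPM against 149 ± 23.0 CPM. Counts on Erdr1, Snhg11, Lars2 and Tmem38b were higher by 4.42, 4.23, 3.60 and 3.44, and for Erdr1, Lars2 and Tmem38b an origin of these reads in rRNA-like or repeated sequence was not tested here. In a joint scaling, the IgG library lay above the polysomes as well, by 4.61 on the log2 scale for Dst, 4.19 for Macf1, 3.97 for Plec, 3.80 for Sptbn1, 3.82 for Dbn1, 3.59 for Col3a1 and 5.87 for Erdr1. Smn1 was higher in the SMN immunoprecipitate by 2.32 (SE 0.27, adjusted p = 4.29e-05), whereas its IgG over polysome log2 ratio was 0.12, from 6 IgG reads. The polysomes came from Smn-/- brains, whereas the IgG library is labelled Smn+/- like the SMN libraries. A rise from genotype alone should thus appear in IgG too, and it was not seen there. That IgG level rests on 6 reads of the only IgG library, whose genotype was not checked. Genotype is therefore not excluded for this gene. In all, 1062 of 6484 genes were higher and 719 lower (edgeR quasi-likelihood test, adjusted p under 0.05). Scaled by library totals, which moved the median log2 fold change of all genes to -0.31, the split was 636 higher and 1578 lower.

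Mitochondrially encoded genes were lower in the SMN immunoprecipitate: 13 of 13 fell, with a median of -1.72 (adjusted p = 6.13e-19, and adjusted p = 0.132 with an estimated correlation). mt-Nd2 had 51.2 ± 27.4 CPM (SD, n = 3) against 562 ± 14.3 CPM (SD, n = 2), and mt-Cytb 170 ± 61.0 CPM against 1349 ± 50.0 CPM. mt-Nd5 was lower by a log2 fold change of -2.89. Their IgG over polysome log2 ratios were -2.84 for mt-Nd2 and -1.86 for mt-Cytb. The IgG median of this list was -1.35. Mt2, a metallothionein, fell by 3.00 on the log2 scale, and Plvap, an endothelial protein, by 3.05, from 1 read in each SMN library. Smim15 fell by 4.44, with 1.67 ± 2.90 CPM against 54.0 ± 4.49 CPM, from 0, 0 and 1 reads in SMN replicates 1 to 3. That level is below the floor of 3 counts over the SMN libraries, 7.08 CPM, so the size of the fall is uncertain. Over the alternatives it ranged from -8.83 to -3.36. Deb1, Tmem74, Ldlrad4 and Gpx8 were lower, with log2 fold changes of -3.61, -3.30, -3.01 and -2.74, from at most 2 reads in any SMN library. Over the alternatives Deb1 ranged from -8.985 to -2.72 and Gpx8 from -3.89 to -1.83. Tmem74 ranged from -3.85 to -2.65 and Ldlrad4 from -3.70 to -2.58.

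Of 26 lists tested, 12 passed camera as higher in the SMN immunoprecipitate and 1 as lower, and 0 with an estimated correlation. In the list of very long coding regions, 38 of 44 members rose and 0 fell, with a median of 1.67 (adjusted p = 1.10e-33, and adjusted p = 0.132 with an estimated correlation), and all 44 lay above the polysomes in IgG. Adjusted over the list alone the count was 38 too. Ahnak and Syne1 rose by 3.03 and 3.01. The transcript counted for Ahnak has a coding region of 16971 nucleotides, but that for Syne1 has 2850 and that for Ank2, also in this list, 3117. Not every member was thus counted on a very long coding region. In the extracellular matrix list, 23 of 32 rose, among them Tnc (2.76) and Fn1 (3.30), and the median was 1.29 (adjusted p = 2.10e-15, and adjusted p = 0.133 with an estimated correlation). Of 41 chromatin regulators 27 rose, such as Kmt2a (2.43) and Trrap (2.42), with a median of 1.00 (adjusted p = 2.38e-14, and adjusted p = 0.300 with an estimated correlation). Of 51 axon growth and cytoskeleton genes 30 rose, such as Ank2 (2.87) and Map1a (2.26), with a median of 0.87 (adjusted p = 1.70e-13, and adjusted p = 0.132 with an estimated correlation). Among 74 histone genes 43 rose, with a median of 0.86 in the fit, and the medians over polysomes in the joint scaling were 0.87 for SMN and 0.22 for IgG (adjusted p = 1.38e-10, and adjusted p = 0.550 with an estimated correlation). Of 79 cytosolic ribosomal protein genes 27 rose and 2 fell, with Rpsa at 396 ± 39.7 CPM (SD, n = 3) against 163 ± 4.68 CPM (SD, n = 2) and a median of 0.47 (adjusted p = 3.76e-04, and adjusted p = 0.597 with an estimated correlation). Adjusted over the list alone, 13 mitochondrially encoded genes fell, and 23 extracellular matrix genes, 31 chromatin regulators and 37 cytoskeleton genes rose. By the same adjustment 49 histone genes rose and 1 fell, and 29 ribosomal protein genes rose and 2 fell. Rises were also called for 17 of 40 adhesion and guidance genes, such as Slit1 (1.74), for 8 of 16 glycolysis genes, such as Gapdh (1.54), and for 7 of 14 vascular markers, such as Igf2 (1.69). Their adjusted p values by camera were 8.75e-04, 0.00421 and 0.00619, and with an estimated correlation adjusted p = 0.550, adjusted p = 0.550 and adjusted p = 0.251. Among receptors and channels 12 of 39 rose and 1 fell, such as Cacna1b (1.68), among progenitor genes 5 of 17 rose, such as Nes (2.80), and among synaptic release genes 10 of 34 rose, such as Pclo (1.83). Camera gave adjusted p values of 0.0107, 0.0200 and 0.0333 for these, and with an estimated correlation adjusted p = 0.550, adjusted p = 0.550 and adjusted p = 0.300. Adjusted over each list alone, the rises in these 6 lists numbered 18, 10, 8, 12, 7 and 10, with 1 fall among the receptors and channels. The synaptic release call was lost with library totals, where the median was 0.031, and without polysome replicate 2, with adjusted p up to 0.0852 by camera. The progenitor call was lost without SMN replicate 2 (camera, adjusted p = 0.0542). With library totals the medians were 0.18 for ribosomal proteins, 0.18 for progenitors, 0.024 for receptors and channels, 0.47 for glycolysis, 0.50 for vascular markers and 0.57 for histones. The ribosomal protein median was 0.51, 0.0089 and 0.61 in SMN replicates 1 to 3. For histones it was 1.38, 0.94 and 0.26, the last close to the IgG median of 0.22 in the joint scaling. The adhesion and guidance median was 0.63, and 0.33 without SMN replicate 1. Of the 1062 higher genes, 1029 had an IgG level above the polysome mean, and of the 719 lower genes, 705 had an IgG level below it. Together this was 97.4% of the called genes, against 58.4% in 20 simulations without any effect in which both immunoprecipitates were set against the same polysome libraries. Across genes, which are not independent replicates, the covariance of the ratios was 0.65 against 0.017 simulated. With 1 polysome library for SMN and the other for IgG, 74 of 75 and 80 of 80 called genes had IgG on the same side, and the covariances were 0.64 and 0.65 against 0.0010 and 0.0019 simulated. Counts moved with single libraries, from 103 higher and 38 lower without polysome replicate 1 to 1755 and 1593 without SMN replicate 2.

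**Figure D3:**
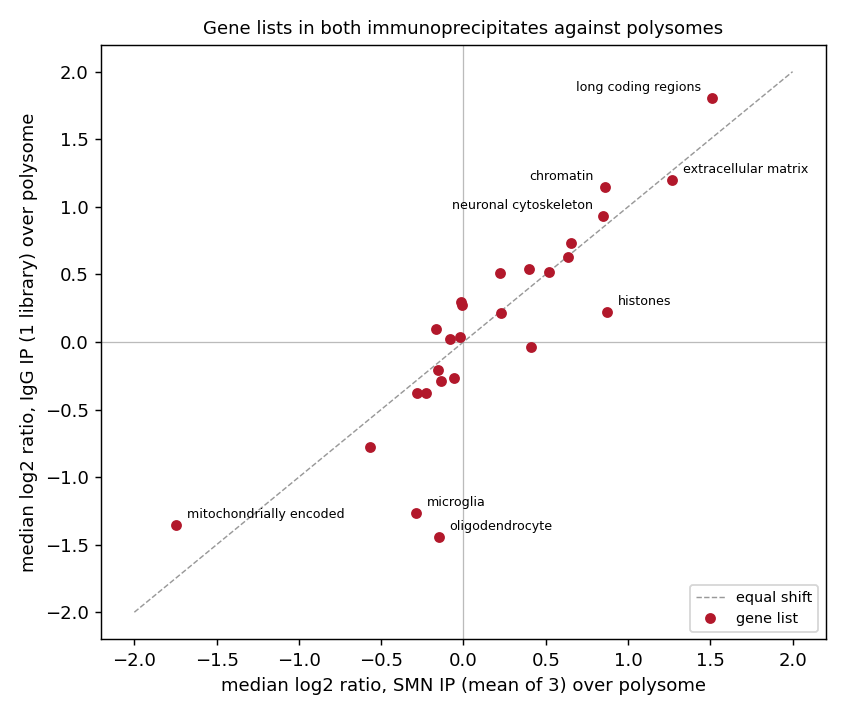
Median log2 ratio over polysome footprints for each of 26 gene lists, in the SMN immunoprecipitate (horizontal axis, mean of 3 libraries) and in the IgG immunoprecipitate (vertical axis, 1 library), with a dashed line at equal shifts. Very long coding regions lie at 1.51 and 1.81 and mitochondrially encoded genes at -1.75 and -1.35, and histones at 0.87 and 0.22.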

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

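Reads on genes without a protein-coding transcript were left out of the comparisons, and the RiboLace and polysome libraries, which have no background control here, held more of them than a count of 0 allows. That limit is 3 reads in a library, which any class with more than a few reads passes, so the shares below are a description and not a test. As means of 2 libraries, small nuclear RNA took 7.55% of reads in RiboLace and 0.356% in polysomes, against 10.5% in the SMN immunoprecipitates and 13.1% in IgG. Small nucleolar and Cajal body RNA took 2.26% and 0.204%, mitochondrial rRNA 4.75% and 0.125%, and mitochondrial tRNA 0.270% and 0.0222%, in RiboLace and polysomes. For microRNA the shares were 1.96% and 0.0746%, for miscellaneous RNA 1.13% and 0.0209%, for long intergenic RNA 0.804% and 0.254%, and for pseudogenes 10.4% and 8.25%. In the SMN immunoprecipitates no such class lay above IgG in each of the 3 libraries. No explanation was tested for these shares.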

How the results depend on the processing

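The SMN over IgG comparison called 0 genes higher in each alternative except without SMN replicate 2, where 2 were higher. Genes lower numbered 0 with DESeq2, with a minimum count of 50, with transcripts as deposited and with counts summed per gene, and 2 with all 8 libraries in 1 fit. Leaving out each SMN replicate gave 0 to 2 higher and 0 to 3 lower, and Gm21887 lost its call without replicate 1 or 3. The cause was not tested. The lists past camera numbered 0 in each of the 3 comparisons with an estimated correlation, from 6, 6 and 13. That form of the test rests on the few libraries of each fit, so the loss does not show correlation between genes as its cause.

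In RiboLace against polysomes, DESeq2 called 6 lower, a minimum count of 50 called 258 higher, all 8 libraries in 1 fit called 63 higher and 1 lower, and limma-voom called 0 and 0. With transcripts as deposited 199 were lower, counts summed per gene gave 252 higher and 64 lower, and all genes with noncoding ones included, an alternative chosen after seeing the data, gave 723 and 562. Leaving out a library gave 31 to 111 higher and 1 to 72 lower. With the replicate block, 58 were higher and 0 lower, and the 58 were all among the 242 calls without it. The deviations of same-numbered RiboLace and polysome libraries correlated at 0.023 across genes. The RiboLace pair differed little beyond sampling noise, so this value cannot tell whether the libraries are paired. The samples share a number and nothing more is known to pair them. Rpl10 turned to -0.56 without RiboLace replicate 1, and Smn1 to 0.30 without RiboLace replicate 2 and to 0.56 with counts summed per gene, with adjusted p of 0.745, 0.911 and 0.648. The same left-out libraries gave Rpl10 1.64 without RiboLace replicate 2 and Smn1 -8.43 without RiboLace replicate 1, where no Smn1 read remained. Atp5b, Cox8a and Atp5a1 were past the threshold in 6, 5 and 8 of 13 alternatives, Cyp4x1 and Mtch2 in 5 of 11, Gap43 in 9 and Hnrnpa2b1 in 8 of 13, and the named lower genes in 4 to 7 of 11. The SMN-enriched set had a median of -0.35 with 500 genes, and -0.43 to -0.011 with a library left out. Its test passed as lower with 500 genes and without RiboLace replicate 1, and also without the histone genes, where the median was -0.39, an alternative chosen after seeing the data. The cause was not tested.

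For the SMN immunoprecipitate against polysomes, DESeq2 called 378 lower and limma-voom 358 lower. Library totals gave 636 higher and 1578 lower, no filter 1215 lower, and a minimum count of 50, where 1220 genes were tested, 194 and 166. Transcripts as deposited gave 1965 and 1429, counts summed per gene 558 and 336, and all genes with noncoding ones included 1921 and 1398. Leaving out a library gave 103 to 1755 higher and 38 to 1593 lower. The replicate block gave 279 higher and 92 lower, with correlations of 0.0046 and 0.031 between the deviations of same-numbered libraries, and 358 of the 371 calls were among those without it. With the replicate block the synaptic release list did not pass, and the progenitor median was 0.78. Smn1 was past the threshold in 13 of 13 alternatives, with adjusted p from 1.29e-11 to 0.00900. Gpx8 was past it in 7 of 11, Deb1 in 10 of 13 and Gapdh in 11 of 14. Other causes were not tested. Over all alternatives, 127 named-gene values in RiboLace against polysomes and 62 in the SMN immunoprecipitate against polysomes lost the threshold with the same direction. RiboLace depth limits calls of lower genes, since a floor of 3 counts over both libraries equals 34.7 CPM.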

Other observations

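The test of a different share of brain regions and those of coding length within 3 gene lists were planned before their results were seen. The other tests below, that of messages chosen by the antibody among them, were chosen after. From the shortest to the longest of 4 equal groups of genes by coding length, the median log2 fold change of the SMN immunoprecipitate over polysomes was -0.38, -0.19, -0.0049 and 0.58, and that of IgG over polysomes -0.49, -0.30, 0.0044 and 0.64. The longest group held 632 of the higher calls. RiboLace over polysomes had medians of -0.17, -0.32, -0.37 and -0.28. In the joint scaling, oligodendrocyte lineage markers had median log2 ratios over polysomes of -0.15 in SMN and -1.44 in IgG, and microglia markers of -0.29 and -1.27, from 10 and 7 genes.

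Smn1 was 4.67-fold higher in the pooled SMN reads than in IgG, from 69 and 6 reads. Counting error is argued against as the cause, since the lower end of the exact 95% interval was 2.04-fold. A hypothesis is that the antibody may hold ribosomes through SMN itself, in part through growing SMN chains. Smn1 lay at percentiles 99.8 and 99.95 of 1894 genes of similar expression in SMN replicates 1 and 3 but at 96.8 in replicate 2, short of the percentile asked for but with a counting interval that reaches it, so this stays open, as does an IgG brain without mouse Smn, since the IgG level of 29.0 CPM was near the SMA polysome levels and no control-genotype polysome library was used here. A different mix of cells stays open too, since Smn1 lay 1.74 SE above the largest cell type median and, without SMN replicates 1, 2 and 3, 0.858, 3.24 and 1.09 SE above it, past the 2 SE asked for without replicate 2 only.

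The cortical neuron gene Tbr1 (log2 fold change -1.21) lay lower, and Zic1 (1.67), Zic2 (1.62) and Calb2 (2.48) higher, in the SMN immunoprecipitate than in IgG, none past the test. With these and similar genes left out, 19 of 20 subcortical and hindbrain genes were positive (median 0.89) and 4 of 31 cortical genes were (median -0.38, and -0.35, -1.13 and 0.011 by library), 0 of them past the test alone, and the lists gave camera p of 0.138 and 0.274 with an estimated correlation. Of 51 and 40 genes listed, 5 of those tested in each list belong to another list, and the most abundant were Nefl (1229 ± 490 CPM, SD, n = 3, against 660 CPM) and Nfix (295 ± 124 CPM against 391 CPM). A different share of brain regions, in the IgG brain or in that of SMN replicate 2, may account for this. The lists differed by at least 0.34 in each SMN library, above at least 99.35% of 10000 pairs of random lists. These differences share 1 IgG library, and the random lists were matched on expression and not on how genes vary together. SMN replicate 2 differed from IgG with a chi-square of 4.10 per gene, and SMN replicate 3 with 1.275. Messages chosen by the antibody cannot be told apart from a different share of regions with 1 IgG library. The difference between the lists ranged by 2.22 between SMN libraries, from 2.55 in replicate 2 to 0.34 in replicate 3. Without replicate 2 the list medians were 0.54 and -0.13, so the lower cortical level rests largely on that library.

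Long coding regions were higher in the SMN immunoprecipitate than in polysomes. Capture through the SMN antibody is argued against as the cause, since the median of these genes in IgG over polysomes was 1.81. A trend with coding length could account for the chromatin regulators, whose median was 0.044 with the trend removed, inside the range of random lists from -0.29 to 0.27. It is argued against as the whole cause for extracellular matrix genes, at 0.60, and neuronal cytoskeleton genes, at 0.98, both above that range for their lists. The genotype of the brains cannot be told apart from the protocol, because no control-genotype polysome library was used here; RiboLace and polysomes of 1 genotype differed by a median of 0.060 for these genes, but by another protocol.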
